A study of Mus musculus with 17 samples.

How the data were processed

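Exome sequencing reads the protein-coding part of the genome after capture of exons. The series holds 17 mouse samples from 6 mice, with 1 pancreatic control sample per mouse and 11 pancreatic tumours. Mice 1, 2 and 6 gave 2 tumours each, mouse 3 gave 3, and mice 4 and 5 gave 1 each. Group, mouse and tumour number were taken from the sample labels. Per the labels' protocols, libraries were captured with an Agilent SureSelect exome kit that the labels call a human kit, although all samples are mouse.

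The deposited table lists 1 call per line, a call being a site at which a tumour differed from its matched control. Per the submitters' processing notes, BWA, GATK and the build GRCh38 were used, with no versions or roles given. Per the file headers and contents, each call comes from Strelka and carries a mouse Ensembl gene identifier. The build GRCh38 is a human one. Of the 240 sites whose gene symbol is in the GRCm38 RefSeq gene table used here, 236 lie inside that gene's GRCm38 span, so positions are given below as the file gives them and read as GRCm38. The filters that turned all candidate sites into the deposited calls are not given in the sources used here. The table holds 0 synonymous calls.

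Allele fractions are deposited as a fraction from 0 to 1, the share of reads at a site with the alternate base in the tumour and, under a second column read from its name as the matched control, in the control. They are printed as percentages. Each call also has a deposited tier of 1 or 2, with 337 calls in tier 1 and 53 in tier 2, and 218 calls have a quality score. The tier was read from a column name and is not taken as a rank of call quality. Read depth is not used here because the depth cells are empty. The depth behind each fraction is therefore unknown, no interval is given for an allele fraction, and counts of calls could not be set against depth. Exon ranks and some genotypes were turned into dates in the deposited sheet and were not used. Of 402 lines, 12 (2.99%) were empty in the copy used and are not analysed here. Which tumours they belong to is not known, so counts are of the calls analysed, and a gene without a call among them is not shown to be unmutated. The 6 controls have no calls of their own and enter only through the control allele fraction.

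A site was identified by position and alternate base. Protein-altering calls were missense, stop, frameshift, inframe, start-lost and splice donor or acceptor calls. The number of calls per tumour was tested as log10(count + 1) over the 4 mice with over 1 tumour, by an exact permutation test over all 1260 partitions of their tumours. Its p is the share of partitions in which mouse accounted for at least as much of the variation. The overlap of 2 tumours was the Jaccard share, the sites in common as a percentage of the sites in either tumour. It was tested one-sided over all 69300 partitions of the 11 tumours. The shares of 6 substitution classes were tested as the counts were. Allele fractions were averaged per mouse from tumour medians and set beside those of the control of the same mouse. The mouse number in the labels gives this pairing, on the reading that tumour and control of a number come from the same animal. The values of mouse 2, given below, leave that reading in doubt for mouse 2. A sign-flip test over the 6 mice had been planned, but calls are chosen for a higher fraction in the tumour, so it carries no information. Tumours of 1 mouse are not independent, and the mouse is the replicate.

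Genes with protein-altering calls in 2 or more mice, and hits in 11 fixed gene lists, were set against 10000 draws, one-sided. Each draw placed each mouse's distinct protein-altering sites at random among genes, counting each gene once per mouse. These genes were the 22396 of the reference table and 10 called genes that had no match in that table. Coding lengths are not used here, so each gene had an equal chance. Control reads and fractions of recurrent genes were compared with those of other genes by permuting genes within mice (100000 resamples, each gene once per mouse), a test added after the data had been seen. Benjamini-Hochberg adjustment was over genes and over lists. Confidence intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only. Tests of simulated data with known answers were run first. With no mouse effect in 11 tumours, 5.9% of 1000 simulations were called, and 100% with a mouse effect of 5 times the spread. For shared sites the shares were 5.3% without and 100% with 8 of 16 sites shared within each mouse. For recurrent genes placed among 22396 genes they were 1.7% at random and 100% with 10 genes planted in 2 mice each. No genome was used here, so the protein-altering share is given without a test against its expected value.

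The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The lists covered pancreatic neuroendocrine tumour genes, mTORC1 and amino acid sensing, glucagon receptor and cAMP signalling, islet cell identity, amino acid transporters, chromatin regulators, cell cycle and p53, receptor tyrosine kinase and RAS signalling, DNA repair, and WNT, NOTCH, TGF-beta and Hippo signalling, and 1 list of long genes served as a check on gene length. The rule names genes with protein-altering calls in 2 or more mice, list members with such a call other than long genes, and the protein-altering call with the highest fraction in each tumour, at most 20 in each of the first 2 parts. Other genes are named as chosen after their values were seen. Blocks of calls were runs of at least 5 sites of a mouse with gaps of at most 5 Mb, a definition chosen after the calls were seen.

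Alternatives were minimum allele fractions of 0.1 and 0.2, substitutions only, sites in over 1 mouse left out, sites with a variant database identifier left out, multigene families (36 symbol prefixes) left out, other units of counting, and leaving out each mouse and each tumour. Tier 1 calls only, calls with a control fraction of 0 only, the data without mice 1 and 2, and gene chances proportional to gene span were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.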

Results

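The study concerns loss of function of GCGR, the glucagon receptor, and pancreatic neuroendocrine tumours that arise from alpha cells, the glucagon-secreting cells of the islet. Exomes of 11 pancreatic tumours from 6 mice were compared with the pancreatic control sample of the same mouse. The calls analysed comprised 390 calls at 258 distinct sites in 209 genes. Alternate reads were listed at 0 in the control for 312 calls and above 0 for 78, with a highest control fraction of 4%. Read depth is unknown.

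The first question was how many mutations each tumour carried and whether tumours of the same animal resembled each other. The tumours of mouse 1 had 108 and 125 calls and those of mouse 2 had 43 and 37. Mouse 3 had 13, 15 and 17 calls in its 3 tumours, mouse 4 had 14, mouse 5 had 7, and mouse 6 had 6 and 5. Over all tumours the median was 15 calls (mean 35.5 ± 42.0, SD, n = 11), and in mice 3 to 6 the mean was 11 ± 4.86 (SD, n = 7 tumours). Protein-altering calls ranged from 5 and 6 in mouse 6 to 98 and 116 in mouse 1. Mouse accounted for 99.3% of the variation of the log10 counts among the 9 tumours of mice 1, 2, 3 and 6 (exact permutation p = 0.000794, the smallest that the partitions can give). Without mouse 3, which moved the median to 25.5 calls, or without mice 1 and 2, the remaining partitions cannot reach a p below 0.0667 and 0.1. The 91 sites common to both tumours of mouse 1 entered both of its counts, as did the 34 of mouse 2. The likeness of counts in these mice is therefore not separate from the sharing of sites. Calls found in no other tumour were 16 and 31 in mouse 1 and 7 and 3 in mouse 2. They were 12, 15 and 15 in mouse 3 and 5 and 4 in mouse 6.

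**Figure D1:**
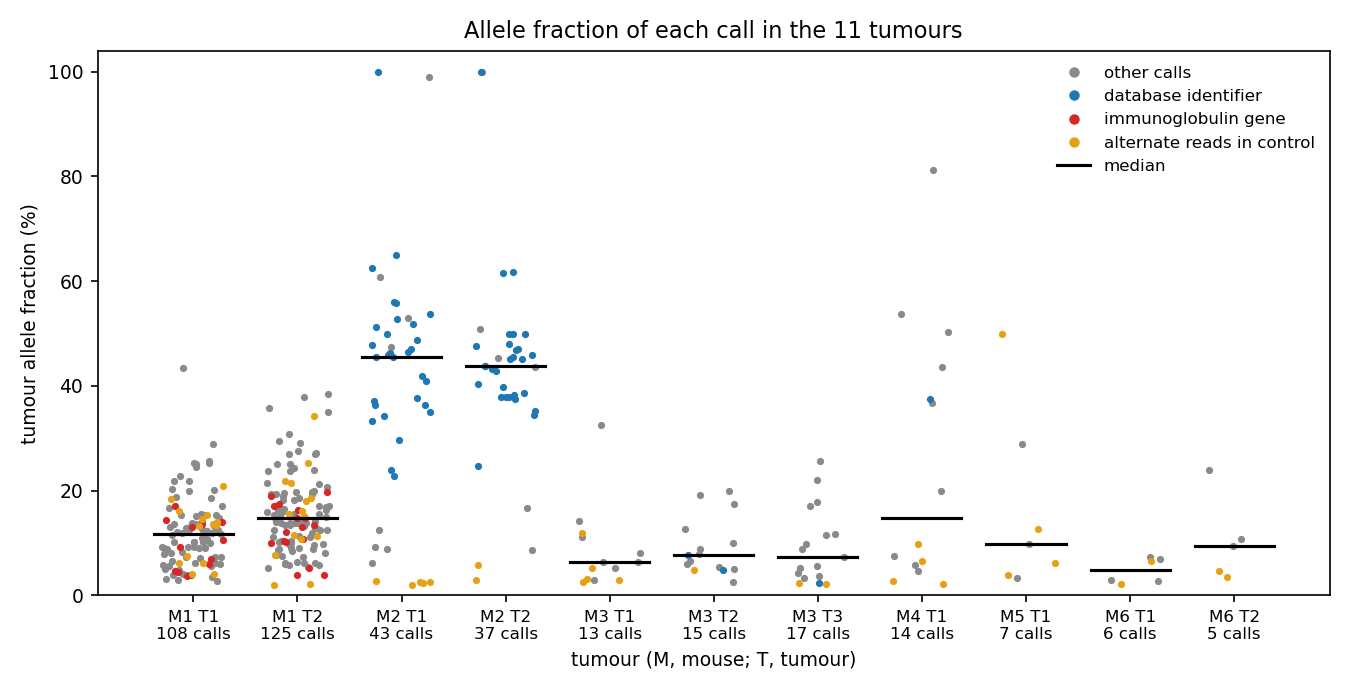
Tumour allele fraction in percent (y axis) of every call in each of the 11 tumours (x axis, with the number of calls), 1 point per call, coloured by database identifier, immunoglobulin gene or alternate reads in the control, with a black line at the median. Calls with a database identifier fill mouse 2 around medians of 45.5% and 43.8%, and calls in immunoglobulin genes occur in mouse 1 alone.

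The next question was whether several tumours of a mouse carried the same mutations. The 2 tumours of mouse 1 had 91 of 142 sites in common (64.1%) and those of mouse 2 had 34 of 46 (73.9%). The 3 tumours of mouse 3 had 1 site in common in 1 of their 3 pairs and 0 in the others, and the 2 tumours of mouse 6 had 0. Of 49 pairs from different mice, 43 had 0 sites in common and the highest number was 2. The mean Jaccard share was 23.6% within mice and 0.249% between mice, a difference of 23.3 percentage points (one-sided exact permutation p = 0.00289). Within-mouse sharing came from mice 1 and 2, and without both the difference was 0.356 points (exact permutation p = 0.352). It was 13.2 to 15.2 points without mouse 1, mouse 2 or either tumour of those mice, 35.1 without tumour 2 of mouse 3 and 45.6 without mouse 3.

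The sites of mice 1 and 2 differed in what they hit, as seen after the calls were examined. In mouse 1, immunoglobulin genes, which encode antibodies, held 17 of 142 sites (12.0%) in 8 genes, and the other mice had 0. Of the 17, 12 were called in both tumours. They included the heavy-chain constant gene Ighm, the joining segments Ighj4 and Igkj4, and the variable segments Ighv1-15, Ighv1-18, Ighv2-2, Ighv1-21-1 and Iglv1. A block of 17 sites lay on chromosome 12 between 113421987 and 114736630, inside the heavy-chain locus, and included Adam6b. Another block of mouse 1, with 5 sites on chromosome 9 between 38539791 and 44334841, held the olfactory receptor genes Olfr910, Olfr933, Olfr944 and Olfr44 and the histone gene H2afx. Shared sites of mouse 1 had a median fraction of 12.5% in tumour 1 and 16.0% in tumour 2. The fraction was higher in tumour 2 at 72 of 91 sites (79.1%, exact 95% interval 69.3 to 86.9). In the control, 14 of these 91 sites had alternate reads, at 1.28% or less.

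In mouse 2, 30 of 46 sites (65.2%, exact 95% interval 49.8 to 78.6) carried an identifier of a variant database, against 1 of 142 in mouse 1 (0.704%, 0.0178 to 3.86) and 4 of 76 in mice 3 to 6 (5.26%, 1.45 to 12.9). They lay largely in 2 blocks in which all sites had an identifier. The block on chromosome 6, from 103711153 to 108485235, held 14 sites in Chl1, Cntn6 and Cntn4, which encode neural cell adhesion proteins, the interleukin 5 receptor gene Il5ra, Setmar, and the calcium channel gene Itpr1. The block on chromosome 18, from 80117170 to 80972275, held 8 sites in Pard6g, Rbfa, Txnl4a, Atp9b and Sall3. Median fractions at the shared sites were 46.7% and 44.5%. Both tumours had fractions between 30 and 70% at 29 of 34 shared sites, and 2 sites, in Kctd12 and Pfn3, were at 99.0 to 100%. In each of these mice only 1 shared site had identical fractions in both tumours. The even split that sampling noise alone would give lies outside the interval of mouse 1 given above, and inside that of mouse 2, where the fraction was higher in tumour 2 at 16 of 34 sites (47.1%, exact 95% interval 29.8 to 64.9). The size of the noise at single sites is not known without depth.

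**Figure D2:**
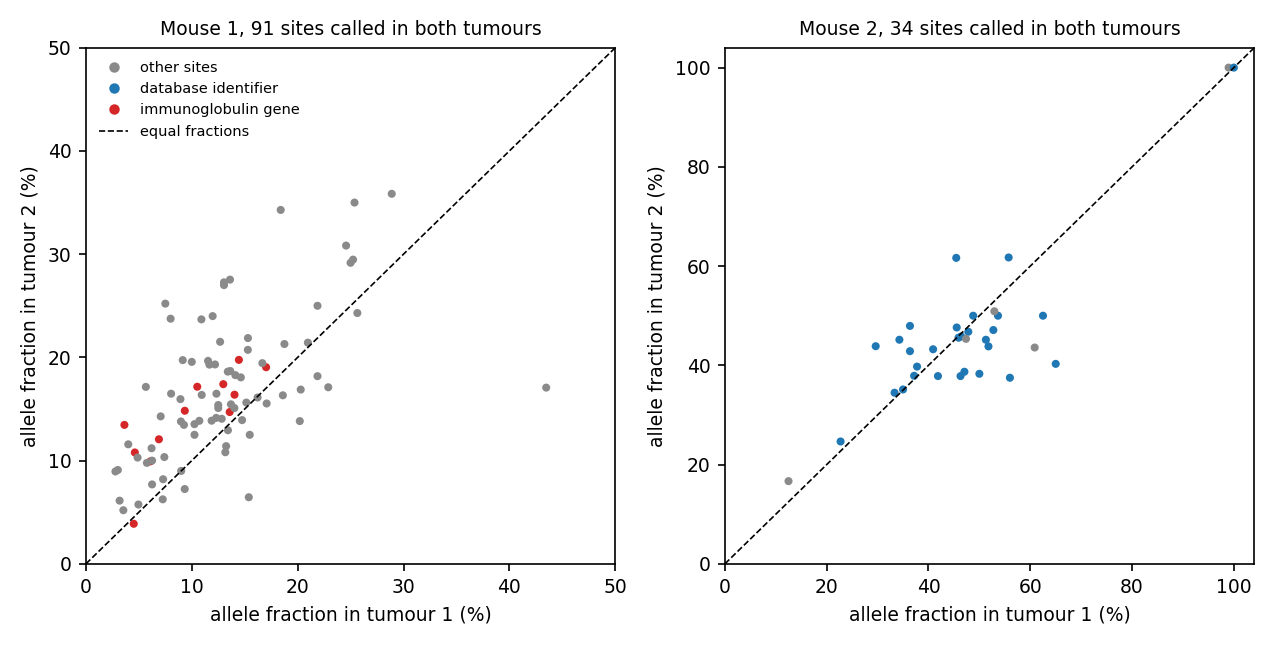
Allele fraction in tumour 2 (y axis, percent) against tumour 1 (x axis, percent) at the 91 sites called in both tumours of mouse 1 (left) and the 34 of mouse 2 (right), 1 point per site, with a dashed line at equal fractions. In mouse 1, 72 points lie above the line, and in mouse 2, 29 points lie between 30 and 70% on both axes.

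**Figure D3:**
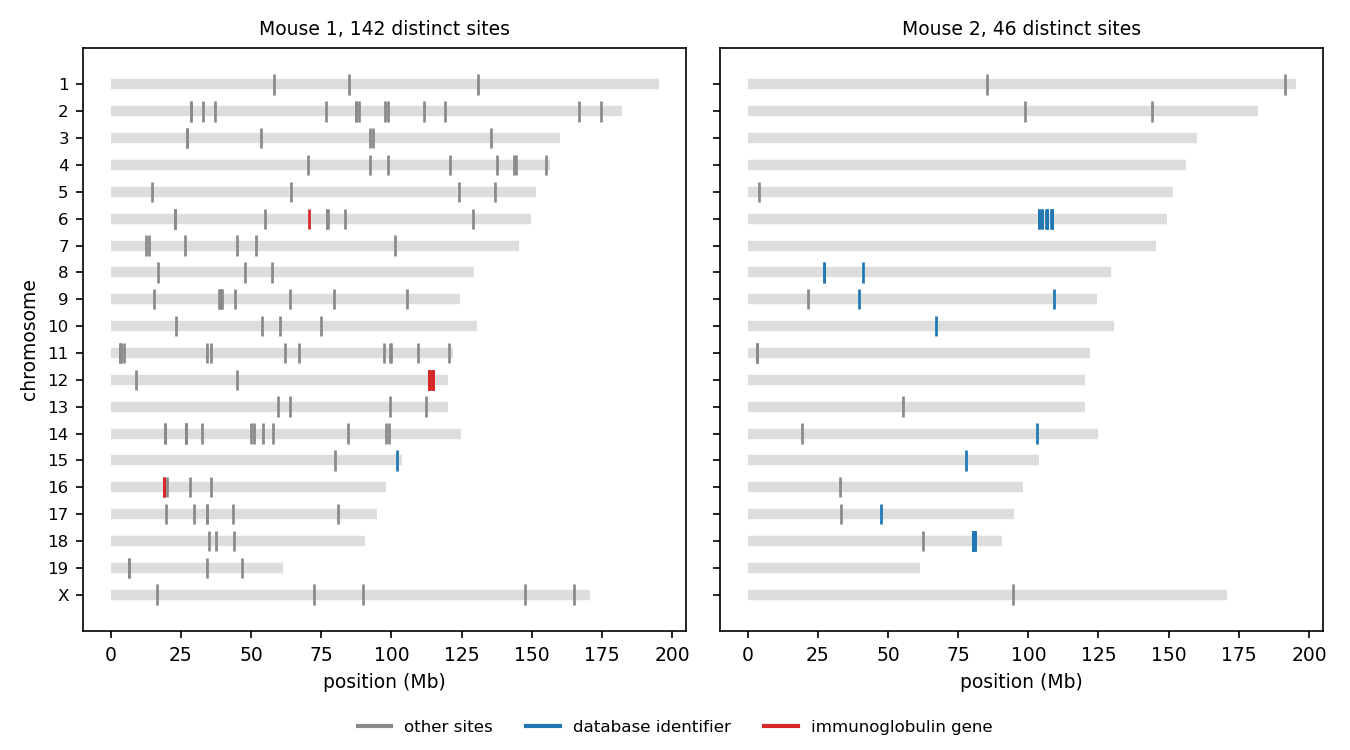
Positions (x axis, Mb) of the 142 distinct sites of mouse 1 (left) and the 46 of mouse 2 (right) along each chromosome (y axis), 1 tick per site; grey bars run to the end of the last annotated gene. The immunoglobulin ticks of mouse 1 crowd on chromosome 12, and the database ticks of mouse 2 crowd on chromosomes 6 and 18.

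A further question was how the calls altered proteins. Counting each site once per mouse, 240 of 264 sites were protein-altering (90.9%, exact 95% interval 86.8 to 94.1). Missense changes made up 221 of them, frameshifts 7, stop codons 6, splice donor or acceptor changes without a frameshift 4, and a lost start and an inframe insertion 1 each. The other 24 lay in splice regions. The share has no test, because 0 synonymous calls are in the table and no genome was used here.

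No substitution class led in most mice. T-to-C changes led in mouse 1 (30.7% against 26.9% C-to-T) and mouse 2 (33.0% against 19.5%). C-to-A and C-to-T changes were level in mouse 3 (27.6 and 27.3%, averaged over its tumours). There, C-to-A equalled C-to-T in tumour 1, exceeded it in tumour 2 and lay below it in tumour 3. C-to-A changes led in mouse 4 (33.3% against 25%), which had 14 calls. C-to-T changes led in mouse 5 (42.9%) and mouse 6 (50%), which had 7 and 11 calls. On average over the mice, C-to-T changes made up 31.9% ± 11.8 (SD, n = 6 mice). T-to-C changes followed at 20.5% ± 12.9, C-to-A at 16.8% ± 11.1, T-to-G at 11.5% ± 9.13, T-to-A at 11.0% ± 8.69 and C-to-G at 8.17% ± 5.43 (each SD, n = 6). Calls were counted in each tumour, so the sites that both tumours had in common entered the shares of both. These were 91 of 142 sites in mouse 1 and 34 of 46 in mouse 2. Similar shares in the tumours of these mice are therefore not separate from the sharing of sites. Mouse accounted for 69.5% of the variation of the 6 shares among tumours of mice with over 1 tumour (exact permutation p = 0.0111). The call ended at allele fractions of at least 0.1 (59.9%, exact permutation p = 0.105) and 0.2 (46.2%, exact permutation p = 0.219), without sites in over 1 mouse (54.4%, exact permutation p = 0.137) and with a control fraction of 0 only (42.2%, exact permutation p = 0.328). It also ended without mouse 3 (67.8%, exact permutation p = 0.0667, the smallest possible) and without mouse 6 or either of its tumours (73.4%, exact permutation p = 0.105).

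Allele fractions show how large a share of the DNA of a sample carried a mutation. Averaged per mouse, the median fraction was 16.1% ± 14.3 in tumours and 0.0651% ± 0.159 in controls (SD, n = 6 mice). The difference was 16.1 percentage points (SD 14.4). Its direction is set by the choice of calls as tumour-specific, so the sign-flip test planned for it carries no information and its p is not given. Medians of single tumours were 11.8 and 14.7% in mouse 1, 45.5 and 43.8% in mouse 2, 14.9% in mouse 4, and 4.84 to 9.76% in the 6 tumours of mice 3, 5 and 6. Without mouse 2 the difference was 10.4 points. The protein-altering calls with the highest fractions outside mouse 2 included the frameshift G1170fs in Cilp, a cartilage matrix gene, at 81.3% in mouse 4 (chromosome 9, 65280130). Those of mouse 1 were V54G in 4930415L06Rik at 43.5% in tumour 1 and Y1854N in Trip12, a ubiquitin ligase gene, at 38.5% in tumour 2. In the 3 tumours of mouse 3 they were A12D in the homeobox gene Rhox3g at 32.6%, G128W in Tmem91 at 20% and I46S in the olfactory receptor gene Olfr186 at 25.7%. They were P79L in Olfr1135 at 28.9% in mouse 5, and R312H in Pomt1, a protein mannosyltransferase gene, at 7.41% and V426L in Thsd7a at 24% in the tumours of mouse 6. In mouse 2 they were G175R in Kctd12 (chromosome 14, 102981918; 100% in both tumours) and R114G in the profilin gene Pfn3 (chromosome 13, 55414827; 99.0 and 100%).

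Recurrence asked whether any gene was altered in several mice. Sfi1, which encodes a centrin-binding protein, had protein-altering calls in 5 of 6 mice (ENSMUSG00000023764, chromosome 11, calls from 3135697 to 3177444). The predicted genes Gm21738 and Gm10801 were called in 3 mice each. Olfr44, an olfactory receptor gene, Vmn2r101, a vomeronasal receptor gene, Muc4, a mucin gene, AW822073 and Gm10800 were called in 2 mice each. These 8 genes compare with a simulated mean of 0.817 and a highest simulated number of 5 (simulation p = 0.0001, the smallest that 10000 draws can give). Sfi1 had an adjusted p of 2.8e-10, Gm21738 and Gm10801 of 0.000413, and the other 5 genes of 0.103. The adjustment was over the 22396 reference genes and the 10 called genes without a match. With chances proportional to gene span the number 8 no longer passed (simulation p = 0.105).

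Calls in these genes differed in how far they lay from the control. The 9 protein-altering calls in Sfi1 had a median tumour fraction of 2.33% and a median control fraction of 1.76%, and all 9 had alternate reads in the control. The 3 calls in Gm10801 had medians of 4.58% and 1.88%, and the 4 calls in Gm21738 a median tumour fraction of 6.80% with a control fraction of 0 in 3 of them. In Olfr44 the missense change S70P of mouse 1 was at 6.25 and 7.69%, and the frameshift I307fs of mouse 2, which has a database identifier, was at 36.4 and 47.9%. In Vmn2r101, T162A of mouse 1 was at 3.02 and 9.09% and the stop codon G226* of mouse 3 at 5.47%, with control fractions of 0. Counting each gene once per mouse, the 8 genes had alternate reads in the control in 15 of 21 cases (71.4%), against 30 of 188 for other genes (16.0%; two-sided permutation p = 2e-05 within mice, the smallest possible), and in 10 of 16 cases without Sfi1 (permutation p = 0.00084). Cases of the same gene in several mice are not independent, so these p-values overstate evidence that rests on 8 genes. By gene, all calls had control reads in Sfi1, Gm10801, AW822073 and Gm10800. In Gm21738, Olfr44 and Muc4 some calls had them, and in Vmn2r101 none did. With families of similar genes left out, 2 genes were left (Sfi1 and AW822073), simulation p = 0.0639, and at allele fractions of at least 0.1 the number was 0.

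The fixed lists asked whether genes of known relevance to these tumours were hit. In mouse 3 tumour 3, Mtor, the kinase of mTORC1, carried S1145P at 3.80% (ENSMUSG00000028991, chromosome 4, 148484660), and Wrn, a DNA repair helicase gene, carried R799C at 17.0% (chromosome 8, 33288886). In both tumours of mouse 1, Slc7a7, a cationic amino acid transporter gene, carried P409S at 18.6 and 16.3% (chromosome 14, 54372963). The same tumours carried K33E in Smad3, a mediator of TGF-beta signalling, at 13.4 and 18.6%, and the frameshift Q788fs in Tet3, a DNA demethylation gene, at 13.2 and 11.4%. The control fraction was 0.565% for Smad3 and 0 for the other 4 genes.

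These 5 genes, each in 1 mouse, were no more than placement at random gave (simulated mean 4.11, simulation p = 0.401). Mtor was the only hit of the 27 pancreatic neuroendocrine tumour genes and of the 56 genes of mTORC1 and amino acid sensing. Slc7a7 was the only hit of 52 amino acid transporters, Tet3 of 56 chromatin regulators, Wrn of 37 DNA repair genes and Smad3 of 44 WNT, NOTCH, TGF-beta and Hippo genes, and each of these 6 lists had an adjusted p of 0.714. No call was analysed in the 39 genes of glucagon receptor and cAMP signalling, the 33 of islet cell identity, the 33 of cell cycle and p53, or the 39 of receptor tyrosine kinase and RAS signalling (0 hits each, adjusted p = 1). The list of 64 long genes had 5 hits against a simulated mean of 0.669 (adjusted p = 0.0066), in Ttn, Pclo and Csmd1 of mouse 1 and Muc4 of mice 2 and 3. It had 1 hit at allele fractions of at least 0.1 (simulation p = 0.338), 0 at 0.2 (simulation p = 1) and 1 without mice 1 and 2 (simulation p = 0.183). With chances proportional to gene span its p was 0.425, and 2 hits were left without mouse 1 and 3 without tumour 1 of mouse 1. Equal chances per gene, which this list was meant to check, also underlie the p-values of recurrent genes and the simulated mean of 4.11. Those values share the limit that this excess shows. The 5 hits of the other lists became 2 without mouse 1 and 3 without mouse 3 or its tumour 3.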

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

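The tests of explanations given here were all chosen after the results they bear on had been seen. Of 13 quantities compared over the 6 mice, 5 had a mouse that stood far from the other mice for their range. A chance rate of about 1 in 20 holds for normally distributed values and is only a rough guide here. The quantities include shares from few sites and shares that depend on each other. The rate does not apply at all to the immunoglobulin share and the control fraction, which were 0 in the other 5 mice. The 5 were the calls per tumour of mouse 1 (116.5, next 40), its share of sites in immunoglobulin genes (12.0%, next 0), the share of database sites in mouse 2 (65.2%, next 7.14%), the median tumour fraction of mouse 2 (44.6%, next 14.9%) and the median control fraction of mouse 5 (0.391%, 0 in the others).

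The 2 tumours of mouse 1 shared 91 sites at a median fraction of 14.4%. DNA of a mouse of another strain in both samples is argued against, because 0 of its 91 shared sites had a database identifier (exact 95% interval up to 3.97%), against 29 of 34 in mouse 2. The other mice had 0 immunoglobulin calls, and the median control fraction at these calls was 0. Neither value tests whether reads were misplaced among similar immunoglobulin segments. Calls are chosen as tumour-specific, so misplaced reads present in a control would have been left out, and the 0 in the other mice prompted the question. Misplaced reads stay open. A clonal B-cell population present in both tumours is a candidate explanation prompted by these calls, and the test run on it did not decide: the ratio of fractions in tumour 2 over tumour 1 was 1.47 at the 12 shared immunoglobulin sites and 1.29 at the 79 other shared sites, and these differed by a factor of 1.14 (bootstrap 95% interval 0.873 to 1.38). Whether both kinds of site come from the same cells, DNA carried between samples, and a shared origin of both tumours all stay open.

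The 2 tumours of mouse 2 shared 34 sites. Mutations acquired in the tumours are argued against for the sites with a database identifier, which made up 29 of the 34 (85.3%, lower end of the exact 95% interval 68.9%) against 5.26% of all sites in mice 3 to 6 (1.45 to 12.9), but not for sites without one, such as the stop codon E221* in Dnm2 (47.4 and 45.3%; chosen after its values were seen). The highest control fraction at the shared sites was 3.23%. Calls are chosen as tumour-specific, and no call analysed had a control fraction above 4%. Loss in the tumours of alleles that the control carries therefore cannot be tested with these control fractions. A control sample from an animal without these strain segments is a candidate explanation, since the median fraction of 46.2% is close to that of an inherited allele on 1 of 2 chromosomes. Tumours from another animal than the label says would give the same values.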

How the results depend on the processing

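The settings with tier 1 calls only, with a control fraction of 0 only, without mice 1 and 2 and with gene-span chances were chosen after the data had been seen, and the others before. No result reversed. The protein-altering share moved by less than its SD over mice (8.58 points) in 27 of 27 alternatives (84.8 to 96.1%), though the lowest, at a fraction of at least 0.2, and the highest, without mice 1 and 2, lie outside its 95% interval, and sharing within mice kept its call in 27 of 28. The median of calls per tumour was 6 and 2 at allele fractions of at least 0.1 and 0.2, and 9 without multigene families. The spectrum's share between mice was no longer called at fractions of at least 0.1 (59.9%) and 0.2 (46.2%), without sites in over 1 mouse (54.4%) and with a control fraction of 0 only (42.2%). The cause was not tested. The recurrent genes were 0 at both minimum fractions, 2 without multigene families, 5 with tier 1 only, 2 with a control fraction of 0 only, 8 with gene-span chances, which end the call, and 98 with each gene once per tumour, which counts shared sites of mice 1 and 2 again. The list hits were 0 at a fraction of at least 0.2 and 8 once per tumour. Without mice 1 and 2, the share of variation between mice was 95.7%, the sharing difference 0.356 points, the spectrum's share 49.8%, the fraction difference 9.63 points, the recurrent genes 3 and the list hits 2. With these 4 mice the exact tests cannot go below 0.1 for counts and spectrum. Leaving out each mouse or tumour in turn gave a median of 14 to 25.5 calls, a share between mice of 98.4 to 99.6%, a spectrum share of 63.1 to 79.2%, a fraction difference of 10.4 to 17.9 points, 5 to 8 recurrent genes and 2 to 5 list hits. Extremes came without mouse 2 (10.4 points, 5 genes), without mouse 3 (25.5 calls, 99.6%, 5 genes) and without mouse 1 (2 hits), and the spectrum call ended without mouse 3, mouse 6 or either tumour of mouse 6. Over all 28 alternatives the fraction difference ran from 9.63 to 33.5 points. Its direction is set by the choice of calls, so the test of this difference says nothing about stability. Minimum depths of 20 and 50 reads, at least 5 alternate reads and chances by coding length were not run, because depth and coding length are not used here. What depth limits stays unknown.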

Other observations

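The tests in this part were all chosen after the calls had been seen, and so were the genes named. Among calls with a high predicted impact on the protein, mouse 1 had 16 calls in 9 genes, mouse 2 had 4 in 2 genes, and mice 3 to 6 had 7 in 7 genes. Both tumours of mouse 1 carried the stop codon W18* in Sco1, a cytochrome oxidase assembly gene (15.2 and 15.6%), and the frameshift R50fs in Apobec3, a cytidine deaminase gene (6.25 and 10%). Outside mice 1 and 2 the set included the frameshift H3fs in Mmadhc, a vitamin B12 metabolism gene, at 11.7% in mouse 3 tumour 3, and D89fs in Naa38, an N-terminal acetylation gene, at 2.80% in mouse 6 tumour 1.

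The genes called in 2 or more mice may be reads shared between near-identical copies or collapsed repeats, since alternate reads in the control were found for 15 of their 21 gene and mouse pairs (71.4%), against 30 of 188 for other genes (16.0%; two-sided p = 2e-05, the smallest possible, in a permutation test of genes within mice). Without Sfi1 it was 10 of 16 (62.5%, permutation p = 0.00084). The permutation tests of this paragraph treat cases of the same gene in several mice as separate, so their p-values overstate the evidence. Mutations selected early and carried by most tumour cells are argued against for the set by its low tumour fractions. Their geometric mean was 0.306 times the median of their own mouse (two-sided permutation p = 2e-05 within mice, the smallest possible). That median rests largely on database sites in mouse 2 (30 of 46) and on shared sites of open origin in mouse 1 (91 of 142). In these mice it may not be a median of mutations of the tumour cells, which limits the comparison. Later selection stays open, as do Olfr44, Vmn2r101 and Gm21738, in which 3 of 11 calls had control reads. With database sites left out, 6 genes were recurrent, without Olfr44 and Muc4. In all, 5 sites were called in over 1 mouse. They were I42L in Gm21738 (mice 1 and 2), V59I in Gm10801 (mice 1 and 6) and, in Sfi1, R152Q (mice 1, 4 and 6), A684E (mice 3 and 4) and a splice-region site at 3143341 (mice 1 and 2). With sites in over 1 mouse left out, 7 genes were recurrent, without Gm10801.

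In mouse 1, calls lay in 5 genes known as mutation targets in germinal-centre B-cell lymphomas. These were splice donor changes in the death receptor gene Fas (13.6 and 27.5%) and the kinase gene Pim1 (7.29 and 8.20%), S31P in the G protein gene Gna13 (24.6 and 30.8%), L88P in Klhl6 (6.20 and 11.2%), and D159G in Tnfrsf14, called in tumour 1 alone (15.3%). A list of 52 such genes, written after the calls were seen, had these 5 in mouse 1 and 0 in the other mice, against a simulated mean of 0.298 in mouse 1 (simulation p = 0.0001, the smallest possible). Of the 52 genes, 8 are also in a list fixed beforehand, among them 0 of these 5. Because the list was written with the calls known, this test carries no weight as evidence.

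Shared sites of mouse 1 on chromosome X had a median fraction of 28.7% (4 sites) against 14.1% on autosomes (87 sites), a ratio of 2.03 with a bootstrap 95% interval of 1.40 to 2.35 (permutation p = 0.00034). Shared calls of 1 male clone, with 1 X chromosome, would give such a ratio and may explain it, and so would DNA of a male animal. The sex of the mice is not used here.

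Mouse 4 had 6 of 14 calls at a fraction of 0.35 or more, all with a control fraction of 0, against 1 of 63 calls in mice 3, 5 and 6. The difference was not tested, because mouse 4 gave 1 tumour. A control exchanged between mouse 2 and another mouse may leave such calls in its partner. Only 1 of the 6, in Acan, had a database identifier, against 65.2% of all sites in mouse 2. A missing identifier does not decide this, as shared mouse 2 sites in Akap9, Pfn3 and Olfr239, at 43.6 to 100%, had none. Cyp51 (53.7%, chromosome 5, 4099206) and Scel (43.6%, chromosome 14, 103605576) lay within 5 Mb of shared mouse 2 sites in Akap9 (4064639) and Kctd12 (102981918). The others of the 6 had no shared mouse 2 site within 5 Mb. This nearness was not tested. A clone that fills most of the tumour of mouse 4 would give such fractions too. The values cannot tell these explanations apart, because the control genotypes are not used here.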
